A study of Homo sapiens with 4 samples.

How the data were processed

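The data are 4 RNA-seq libraries of mantle cell lymphoma cells from biopsies, 2 titled p_Ib (lymph node) and 2 titled r_Ib (bone marrow and spleen by title and source name). Per the labels' protocols, cells were selected with CD19 beads, RNA was converted with the TruSeq mRNA kit, and libraries were sequenced as pairs of 50-base reads on a HiSeq2000. This kit selects poly(A) RNA and does not mark strand. The submitters' processing notes name CASAVA 1.8.2, BWA, SAMtools and GATK, with no role or order. The counting program, the gene annotation and the genome build were not given in the sources used here, so coordinates are printed as the files give them, with no build.

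The authors deposited, for each library, a table of 25619 genes with an Entrez gene number, a symbol and a raw read count. Counts of intronic and of opposite-strand reads were deposited by the authors beside it. The deposited tables also hold RPM values, which the authors scaled to 42518573, 43124838, 45896295 and 105920914 reads for p_Ib1, p_Ib2, r_IbBM and r_IbSP, more than the counts in genes add up to. The deposited RPKM values further divide by a transcript length, which was recovered from the ratio of RPM to RPKM and used only to match genes by length. Opposite-strand counts were close to 50% of the total in each library. Intronic counts made up 25.1% in p_Ib1, 30.5% in p_Ib2, 26.9% in r_IbBM and 31.7% in r_IbSP of intronic and gene counts together. Genes that overlap another listed gene (26.1%) can share reads with it, and near-identical copies such as HSPA1A and HSPA1B are uncertain, because the counting rule was not given in the sources used here.

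In each library 101 lines without a symbol, with 0.0597 to 0.114% of counts, were left out. Genes that depend on the sex chromosomes' makeup were left out throughout, 139 in all, which left 25379 genes. Immunoglobulin and T cell receptor genes, HLA genes and genes with common germline deletions stayed in the tests but are not named or tabulated, since they can mark a person or clone. The columns of sequence variants were not used. Counts in genes totalled 31200850 to 75420010 per library, and a floor of 3 counts corresponded to 0.0412 to 0.0927 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

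The main test was edgeR 4.0.16 (R 4.3.3), quasi-likelihood, on the deposited counts with TMM scaling and filterByExpr at a minimum count of 10, which kept 16038 genes, with Benjamini-Hochberg adjustment at 0.05, two-sided. The fit took all 4 libraries with no covariate, because tissue is nested in group and donors are not given. CPM values are scaled by TMM. The biological coefficient of variation was 36.5%. The script was tested on simulated data with the means, library sizes and spread of the r_Ib minus p_Ib comparison, in which 200 of 16038 genes were changed. Both groups were simulated with the same spread. In the data, genes at least 2-fold apart numbered 1507 within r_Ib and 19 within p_Ib, so the simulated rates may not hold for these libraries. The quasi-likelihood test recovered 2% of genes changed 2-fold, 44% of those changed 4-fold and 96% of those changed 16-fold, with 18 false calls among 139. DESeq2 made 59 false calls among 206, the exact test 43 among 185 and limma-voom 18 among 138, so each went past the 5% that the adjustment aims at. Camera called 2 of 2 lists whose members were all shifted 4-fold, and 0 others. This does not show how camera does at smaller shifts. Genes were simulated independently of each other, so this cannot show how camera does where the members of a list vary together.

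A set of 37 gene lists was fixed before the data were examined. They cover lymphoma biology, sample quality and other cell types. Of 822 listed names, 784 matched by symbol, 10 by gene number and 10 repeated another member, and 18 did not match. The mitochondrial genome list had 0 measured members, which left 36. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, beside camera with the correlation estimated and fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. Within groups, libraries were compared 1 against 1 with no test, as log2 ratios of CPM plus 0.5. A list's median was placed among 10000 random lists matched on mean expression in 20 bins. Other tools were DESeq2 1.42.0, Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

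The genes named were set by a rule written before the data were examined. It takes 24 key genes of the disease and pathway whatever their values. It also takes up to 10 genes per direction past the threshold, or else the 5 with the smallest p. Those genes needed a mean of at least 10 CPM and both libraries of 1 group above both of the other. Up to 4 members of each described list are taken by size of change. In the 1 against 1 comparisons up to 8 genes per direction are taken, with a mean of at least 10 CPM. Alternatives were leaving out each library, other filters, DESeq2 size factors, upper quartile scaling, the DESeq2 Wald test, limma-voom, edgeR's exact test, a threshold of 0.10, and leaving out immunoglobulin and T cell receptor genes. Added after seeing the data were leaving out the heat shock list before scaling, limma trend and the robust quasi-likelihood test.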

Results

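Gene expression was measured by poly(A)-selected RNA sequencing in 4 libraries of mantle cell lymphoma, a B cell cancer in which the cyclin D1 gene is typically overexpressed. Lymphoma cells had been enriched from biopsies with CD19 beads, and tumour cells positive for CD19 and CD5 and negative for CD23 made up the large majority by flow cytometry, per the labels. The titles divide the libraries into 2 groups of 2, p_Ib and r_Ib, and the labels used here do not spell out either prefix. Both p_Ib libraries came from lymph node. The r_Ib libraries were titled r_IbBM and r_IbSP, with source names of bone marrow and spleen, although a second label of r_IbSP also reads bone marrow. Tissue therefore changed together with group, and the labels do not say which libraries came from separate donors. The p-values of single genes thus measure only the spread between these samples. Those of camera with the preset correlation rest on the spread between genes and on the assumed correlation of 0.01, and do not measure how samples vary. The protocol text also describes culture of primary cells, and the labels do not say whether these libraries were made before or after it. Counts in genes totalled 32926569 in p_Ib1, 31200850 in p_Ib2, 34850436 in r_IbBM and 75420010 in r_IbSP. Levels are given in CPM, counts scaled to the library's total times its TMM factor, and a gene at 10 CPM rested on 324 to 729 counts. The files used human gene coordinates counted from 1 whose genome build was not named. The series title refers to the cell cycle, PI3K and BTK, the kinase downstream of the B cell receptor.

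The comparison of r_Ib with p_Ib asks which genes differed between the groups that the titles give. Genes named here by p-value had a mean of at least 10 CPM and r_Ib values that did not overlap those of p_Ib. Among them, the 5 with the smallest p-values that were higher in r_Ib were JUP, PRAME, CXCL12, LRRC3 and ELL2. JUP encodes the junction protein plakoglobin, PRAME is a tumour antigen, CXCL12 a chemokine and ELL2 an elongation factor. CXCL12 is also a member of the list of stromal and endothelial markers, so its level need not come from lymphoma cells. JUP (Entrez 3728, chromosome 17, 39910859 to 39942964) stood at 6.39 ± 0.13 CPM in p_Ib and 66.3 ± 0.20 CPM in r_Ib (mean ± SD, n = 2 in each), a log2 fold change of 3.37 ± 0.21 (SE) with an adjusted p of 0.0711. PRAME (Entrez 23532, chromosome 22, 22890123 to 22901696) had 20.5 ± 1.3 CPM in p_Ib and 219 ± 27.1 CPM in r_Ib, a log2 fold change of 3.42 ± 0.22. For CXCL12 the group means were 0.558 and 19.8 CPM, for LRRC3 6.03 and 49.3 CPM and for ELL2 10.2 and 86.3 CPM. The 5 lower in r_Ib were the anchoring protein AKAP6, the BMP receptor BMPR2, the transcription factor TSHZ2, the TACI receptor TNFRSF13B and the phosphatase PTPN1. AKAP6 (Entrez 9472, chromosome 14, 32798479 to 33302268) stood at 63.6 ± 3.5 CPM in p_Ib and 1.70 ± 0.31 CPM in r_Ib, a log2 fold change of -5.21 ± 0.27 with an adjusted p of 0.0711. Mean levels in p_Ib and r_Ib were 146 and 23.5 CPM for BMPR2, 114 and 17.6 CPM for TSHZ2, 50.7 and 6.79 CPM for TNFRSF13B, and 356 and 52.3 CPM for PTPN1. BMPR2 and PTPN1 each overlap an uncharacterised locus, and the counts did not use strand.

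None of these 10 genes passed the threshold of 0.05 in edgeR's quasi-likelihood test, with adjusted p-values of 0.0711 to 0.113. With no filter on low counts 16 genes passed the same test, all 10 of these among them, with a largest adjusted p of 0.0348. Of 16038 genes tested, 0 passed, 12 had an adjusted p under 0.10, and 2296 (14.3%) had an unadjusted p under 0.05, 1285 of them higher and 1011 lower in r_Ib. Limma-voom also called 0 genes, while the DESeq2 Wald test called 797 (442 higher, 355 lower) and edgeR's exact test called 509 (299 higher, 210 lower). All 10 named genes passed with DESeq2, with a largest adjusted p of 5.74e-19, and with the exact test, with a largest of 1.79e-12. In data simulated at the estimated spread, equal in both groups, 59 of 206 DESeq2 calls and 43 of 185 exact test calls were false. With the quasi-likelihood test 18 of 139 calls were false. The number of calls depended on whether both r_Ib libraries were kept. Without r_IbBM 6044 genes passed and without r_IbSP 7589 passed, because the spread then came from the p_Ib pair alone, and leaving out either p_Ib library gave 0. Of the 24 key genes named in the following paragraphs, 0 passed in the quasi-likelihood test, with limma-voom or with the exact test, and CCND1, MAP3K14 and MYC passed with DESeq2. Without r_IbBM 15 of the 24 passed and without r_IbSP 16 passed.

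**Figure D1:**
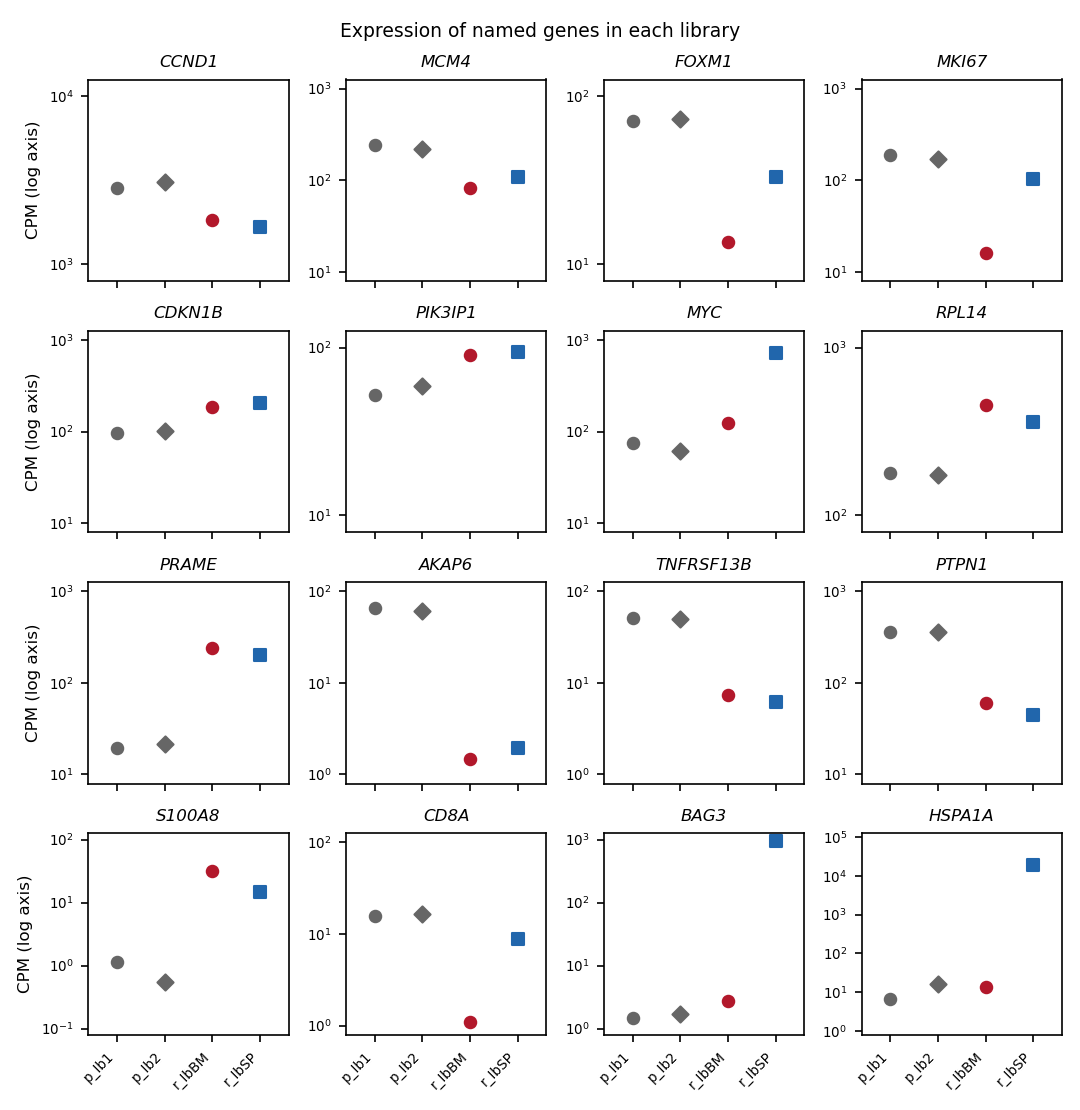
Expression of 16 named genes in each library, in CPM on a log axis, with a point for each of the 4 libraries (p_Ib in grey, bone marrow r_Ib in red, spleen r_Ib in blue). PRAME stood at 238 and 200 CPM in r_Ib against 19.5 and 21.4 CPM in p_Ib, while BAG3 and HSPA1A were high in the spleen library and MKI67 was lowest in the bone marrow library, at 15.9 CPM.

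Genes of DNA replication were lower in r_Ib than in p_Ib. Of 32 measured members of the list for G1/S and DNA replication, 29 were lower in r_Ib. The median log2 fold change was -0.62 and the list was called by camera with a preset correlation (adjusted p = 8.17e-07), but not with an estimated correlation (adjusted p = 0.533). Adjusted over the list alone, 4 members were lower, and 0 passed over all genes tested. The replicative helicase subunit MCM4 had 233 ± 16.8 CPM in p_Ib and 96.1 ± 18.6 CPM in r_Ib (log2 fold change -1.28 ± 0.23, adjusted p = 0.265). The replication factor CDC45 had 16.1 and 5.99 CPM, the chromatin assembly subunit CHAF1A 90.0 and 40.2 CPM, and thymidine kinase TK1 74.9 and 34.5 CPM. Mitotic genes followed the same direction, with 34 of 36 members of the G2/M list lower, a median of -0.68 and a camera adjusted p of 2.81e-05 (adjusted p = 0.653 with an estimated correlation). This difference lay mostly in bone marrow. The list's median log2 ratio to the p_Ib mean was -1.91 in r_IbBM and -0.16 in r_IbSP, and without r_IbBM the call was lost (adjusted p = 0.157). The proliferation marker MKI67 stood at 186 and 171 CPM in p_Ib, 15.9 CPM in r_IbBM and 102 CPM in r_IbSP. FOXM1, a transcription factor of mitotic genes, stood at 70.8, 73.7, 13.5 and 33.1 CPM in the same order, and the kinetochore protein CENPF at 144, 123, 14.6 and 67.5 CPM. FOXM1 and CENPF each overlap another listed locus.

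G1 cyclins, cyclin-dependent kinases and their inhibitors were not called as a list, with 11 of 22 members higher and 11 lower (adjusted p = 0.181). CCND1, cyclin D1 (Entrez 595, chromosome 11, 69455873 to 69469242), had 2968 ± 175 CPM in p_Ib and 1743 ± 124 CPM in r_Ib, a log2 fold change of -0.77 ± 0.25 that did not pass (adjusted p = 0.312). CCND3 had 90.6 and 136 CPM, and CCND2 had 24.5 CPM in p_Ib, 9.03 CPM in r_IbBM and 55.5 CPM in r_IbSP. CDK4, the cyclin D-dependent kinase whose gene overlaps TSPAN31, had 80.7 and 104 CPM, and CDK6 had 3.63 CPM in p_Ib, 1.66 CPM in r_IbBM and 5.67 CPM in r_IbSP. The log2 fold change of CDK6 was -1.12 without r_IbSP (adjusted p = 0.0117) and 0.62 without r_IbBM. The inhibitor CDKN1B, p27, had 98.4 ± 4.6 CPM in p_Ib and 194 ± 13.9 CPM in r_Ib (log2 fold change 0.98 ± 0.19, adjusted p = 0.273). The retinoblastoma gene RB1, which overlaps LPAR6, had 181 and 73.6 CPM, and the S phase regulator E2F2 had 78.2 CPM in p_Ib, 15.3 CPM in r_IbBM and 34.3 CPM in r_IbSP. The inhibitor CDKN1C had 1.57 CPM in p_Ib, 4.52 CPM in r_IbBM and 36.9 CPM in r_IbSP, and without r_IbSP its log2 fold change was 1.52 in place of 3.72. Adjusted over the list alone, 1 member was higher and 1 lower.

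Genes of PI3K, AKT and mTOR signalling were not called, with 11 of 32 members higher and 21 lower (median -0.12, adjusted p = 0.279). PIK3IP1, an inhibitor of PI3K, had 55.6 ± 5.0 CPM in p_Ib and 92.6 ± 2.4 CPM in r_Ib (log2 fold change 0.73 ± 0.18, adjusted p = 0.299). The catalytic subunit PIK3CA had 44.9 and 57.3 CPM. PIK3CD, which overlaps CLSTN1 and C1orf200, had 408 CPM in p_Ib, 545 CPM in r_IbBM and 404 CPM in r_IbSP. PIK3CG had 79.2, 20.95 and 51.3 CPM in the same order. The translation repressor EIF4EBP1 had 11.6 and 23.9 CPM. Targets of FOXO transcription factors, which PI3K signalling restrains, were called as higher in r_Ib, with 14 of 18 members higher and a median of 0.78 (adjusted p = 0.0392, and adjusted p = 0.533 with an estimated correlation). Each fit that left out a library lost this call, with adjusted p-values of 0.0646 to 0.119, as did the fit with no filter (adjusted p = 0.0597). The FOXO target TXNIP, a regulator of glucose uptake, stood at 26.1 and 23.7 CPM in p_Ib, 60.7 CPM in r_IbBM and 319 CPM in r_IbSP. The homing receptor CCR7 stood at 176 and 160 CPM in p_Ib, and at 730 and 334 CPM in r_Ib.

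B cell receptor signalling genes were not called, with 16 of 32 members higher and 16 lower (adjusted p = 0.604). BTK had 194 ± 3.9 CPM in p_Ib and 241 ± 29.5 CPM in r_Ib (adjusted p = 0.503), PLCG2 had 253 and 240 CPM, and CARD11 had 221 and 204 CPM. The chemokines CCL3 and CCL4, which B cells release on receptor engagement, stood at 12.4 and 28.0 CPM in p_Ib, 32.9 and 94.8 CPM in r_IbBM and 183 and 290 CPM in r_IbSP. The receptor-induced NR4A1, which overlaps LOC100506166, stood at 170 CPM in p_Ib, 350 CPM in r_IbBM and 1438 CPM in r_IbSP. Without r_IbSP the log2 fold changes of CCL3, CCL4 and NR4A1 were 1.41, 1.76 and 1.04, in place of 3.13, 2.78 and 2.40. NF-kB target genes were called as higher, with 25 of 32 members higher and a median of 0.57 (adjusted p = 0.00963, and adjusted p = 0.653 with an estimated correlation), and the call was lost without r_IbSP (adjusted p = 0.573). The cytokine TNF stood at 6.72, 11.5 and 9.93 CPM in p_Ib1, p_Ib2 and r_IbBM and at 617 CPM in r_IbSP. Alternative NF-kB signalling was not called, with 8 of 15 members higher (adjusted p = 0.765). Its kinase MAP3K14, whose gene overlaps C17orf46 and LOC100133991, had 112 ± 6.5 CPM in p_Ib and 64.5 ± 1.9 CPM in r_Ib (log2 fold change -0.80 ± 0.18, adjusted p = 0.285). Its regulators TRAF3 and BIRC3 had 68.2 and 256 CPM in p_Ib, 113 and 320 CPM in r_IbBM and 52.4 and 760 CPM in r_IbSP, and the BAFF receptor TNFRSF13C had 268, 180 and 88.0 CPM in the same order.

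Genes of mantle cell lymphoma identity were not called, with 12 of 19 members lower (adjusted p = 0.0518), although they were called as lower without p_Ib2 (adjusted p = 0.0307) and without r_IbBM (adjusted p = 0.0447). They were also called with no filter (adjusted p = 0.0307), with the stricter filter (adjusted p = 0.0283) and with upper quartile scaling (adjusted p = 0.0408). With an estimated correlation they were not called (adjusted p = 0.533). SOX11, the diagnostic transcription factor, stood at 471 and 430 CPM in p_Ib, 272 CPM in r_IbBM and 663 CPM in r_IbSP. CD19 had 385 ± 18.2 CPM in p_Ib and 351 ± 28.7 CPM in r_Ib. CD5 had 221 CPM in p_Ib, 304 CPM in r_IbBM and 196 CPM in r_IbSP. FCER2, which encodes CD23, had 1.79 CPM in p_Ib, 7.37 CPM in r_IbBM and 2.88 CPM in r_IbSP, a log2 fold change of 1.51, or 0.66 without r_IbBM and 2.04 without r_IbSP. The B lineage factor PAX5 had 317 ± 21.5 CPM in p_Ib and 142 ± 8.7 CPM in r_Ib (log2 fold change -1.16 ± 0.20, adjusted p = 0.257), and the surface receptor ROR1 had 62.9 and 20.3 CPM. Apoptosis regulators were not called, with 12 of 24 members higher (adjusted p = 0.627). The survival genes BCL2 and MCL1 had 388 and 796 CPM in p_Ib and 330 and 1031 CPM in r_Ib. Homing and adhesion genes were not called, with 17 of 23 members lower (adjusted p = 0.0637, or 0.0359 with no filter, which called it), and the chemokine receptor CXCR4 stood at 2925 and 3467 CPM in p_Ib, 4578 CPM in r_IbBM and 1608 CPM in r_IbSP. Germinal centre genes were not called, with 12 of 18 lower (adjusted p = 0.234). Adjusted over that list alone 3 members were lower, among them BCL7A at 103 ± 1.5 CPM in p_Ib and 27.3 ± 4.05 CPM in r_Ib, while MEF2B, which overlaps 4 other listed loci, had 145 and 50.7 CPM. The plasma cell programme was not called, with 14 of 23 members higher (adjusted p = 0.745), and its regulator XBP1 stood at 9.84 and 7.91 CPM in p_Ib, 11.5 CPM in r_IbBM and 50.0 CPM in r_IbSP.

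Ribosomal protein genes, MYC targets and oxidative phosphorylation genes were called as higher in r_Ib by camera with the preset correlation. Of 56 cytosolic ribosomal protein genes, 54 were higher (median log2 fold change 0.57, adjusted p = 1.28e-06, and adjusted p = 0.653 with an estimated correlation). RPL14 had 177 ± 2.75 CPM in p_Ib and 408 ± 65.8 CPM in r_Ib, and RPL32, which overlaps SNORA7A, had 107 CPM in p_Ib, 362 CPM in r_IbBM and 151 CPM in r_IbSP. The list's median log2 ratio to the p_Ib mean was 0.85 in r_IbBM and 0.24 in r_IbSP, against 0.15 between p_Ib1 and p_Ib2. MYC targets were higher at 28 of 32 members (median 0.43, adjusted p = 0.000148, and adjusted p = 0.533 with an estimated correlation). MYC itself stood at 75.2 and 61.1 CPM in p_Ib, 123 CPM in r_IbBM and 718 CPM in r_IbSP, a log2 fold change of 2.62 ± 0.85 (adjusted p = 0.312), or 0.85 without r_IbSP and 3.37 without r_IbBM. The ribosome assembly factor RRS1 had 19.4 and 48.6 CPM, while the mitochondrial chaperones HSPD1 and HSPE1, which overlap each other and also belong to the heat shock list, had 105 and 28.3 CPM in p_Ib, 168 and 60.9 CPM in r_IbBM and 1397 and 207 CPM in r_IbSP. Without r_IbSP their log2 fold changes were 0.68 and 1.11, in place of 2.90 and 2.24. Oxidative phosphorylation genes were higher at 35 of 39 members (median 0.45, adjusted p = 0.000203, and adjusted p = 0.653 with an estimated correlation), and without r_IbBM the call was lost (adjusted p = 0.190). COX7B and UQCRH had 13.9 and 25.8 CPM in p_Ib, 42.3 and 69.4 CPM in r_IbBM and 18.4 and 32.8 CPM in r_IbSP.

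Stress and response lists were also called as higher in r_Ib, and each of those named here lost its call without r_IbSP. Heat shock genes were higher at 16 of 16 members (median 3.49, adjusted p = 0.00167, and adjusted p = 0.653 with an estimated correlation, or 0.278 without r_IbSP). Targets of p53 were higher at 18 of 22 members (median 0.60, adjusted p = 0.0120, adjusted p = 0.533 with an estimated correlation, 0.228 without r_IbSP), and the p53 target SESN2 had 4.47 CPM in p_Ib, 9.78 CPM in r_IbBM and 34.6 CPM in r_IbSP. Without r_IbSP the log2 fold change of SESN2 was 1.13, in place of 2.31. Immediate early and dissociation genes were higher at 21 of 27 members (median 1.45, adjusted p = 0.0392, adjusted p = 0.653 with an estimated correlation, 0.900 without r_IbSP). The call of these genes was also lost without p_Ib1 (adjusted p = 0.173), with no filter (adjusted p = 0.0574) and with the stricter filter (adjusted p = 0.0690). The stress-induced factor ATF3 stood at 12.7 and 14.6 CPM in p_Ib, 60.2 CPM in r_IbBM and 674 CPM in r_IbSP. Interferon response genes were higher at 29 of 34 members (median 0.37, adjusted p = 0.00963, adjusted p = 0.653 with an estimated correlation, 0.683 without r_IbSP), and the call was also lost without p_Ib2 (adjusted p = 0.192). OASL, an interferon-induced gene, had 4.30 CPM in p_Ib, 10.4 CPM in r_IbBM and 22.0 CPM in r_IbSP. Glycolysis and hypoxia genes were higher at 25 of 30 members (median 0.27, adjusted p = 0.0233, and adjusted p = 0.653 with an estimated correlation). That call was lost without r_IbSP (adjusted p = 0.149) and without p_Ib2 (adjusted p = 0.121), and ANKRD37, which overlaps UFSP2, had 6.59 and 35.0 CPM. The unfolded protein response (17 of 24 higher, adjusted p = 0.234), cholesterol synthesis (15 of 22 higher, adjusted p = 0.249), class II antigen presentation (5 of 13 higher, adjusted p = 0.858), chromatin genes mutated in this lymphoma (11 of 18 lower, adjusted p = 0.0591, or 0.0359 and called with no filter) and replication-dependent histones (13 of 15 higher, adjusted p = 0.690) were not called. The histones were called as higher without r_IbBM (adjusted p = 7.08e-05) and as lower without r_IbSP (adjusted p = 0.00770).

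Markers of other cell types differed alongside these groups. Erythroid markers were higher in r_Ib at 11 of 11 measured members, out of 18 listed. Adjusted over the list alone 9 passed, and camera called the list (adjusted p = 1.75e-06, and adjusted p = 0.533 with an estimated correlation). The list's median log2 fold change was 7.03. It was 4.44 with the 3 members at 0 counts in p_Ib set at a floor of 3 counts per library. The haemoglobin gene HBB stood at 0.236 and 0.0618 CPM in p_Ib, 301 CPM in r_IbBM and 35.8 CPM in r_IbSP. Monocyte and macrophage markers were higher at 19 of 22 members, 5 of them when adjusted over the list alone (median 1.82, adjusted p = 3.14e-06, and adjusted p = 0.533 with an estimated correlation). The list's median log2 ratio to the p_Ib mean was 0.81 in r_IbBM and 1.82 in r_IbSP, and 15 of 22 members were higher in r_IbSP than in r_IbBM. The calprotectin subunits S100A8 and S100A9 were instead higher in r_IbBM. They had 0.838 and 0.813 CPM in p_Ib, 31.8 and 21.6 CPM in r_IbBM and 14.7 and 12.4 CPM in r_IbSP. Neutrophil precursor markers were higher at 7 of 7 measured members, out of 21 listed (median 2.64, adjusted p = 0.00120, and adjusted p = 0.533 with an estimated correlation). Among them was LTF at 7.43 CPM in r_IbBM and 0.453 CPM in r_IbSP. A gene near 0 in p_Ib could pass the filter on low counts only through r_Ib. The counts of higher erythroid and neutrophil members were thus partly set by that filter. With no filter both lists were still called as higher. Megakaryocyte and platelet markers were higher at 7 of 8 members (median 1.67, adjusted p = 0.0233, adjusted p = 0.653 with an estimated correlation). Their call was lost without r_IbBM and with the stricter filter (adjusted p = 0.0693). The list's median log2 ratio to the p_Ib mean was 1.53 in r_IbBM and 0.36 in r_IbSP, and 6 of 8 members were higher in r_IbBM than in r_IbSP. THBS1 was instead higher in r_IbSP, at 1.36 CPM in p_Ib, 8.41 CPM in r_IbBM and 16.8 CPM in r_IbSP. T cell markers were lower at 14 of 22 members (median -0.47, adjusted p = 0.00429, adjusted p = 0.653 with an estimated correlation), and the direction turned without r_IbBM (adjusted p = 0.789). CD8A stood at 15.8 and 16.6 CPM in p_Ib, 1.10 CPM in r_IbBM and 8.72 CPM in r_IbSP, and CTLA4 at 9.78, 13.3, 0.594 and 8.05 CPM in the same order. Memory and marginal zone B cell markers were lower at 8 of 12 members (median -0.11, adjusted p = 0.0381, adjusted p = 0.653 with an estimated correlation), with FCRL4 at 76.6 CPM in p_Ib, 3.86 CPM in r_IbBM and 34.6 CPM in r_IbSP. The log2 fold change of FCRL4 was -1.99, or -4.31 without r_IbSP and -1.17 without r_IbBM. That call was lost without r_IbBM (adjusted p = 0.702) and without p_Ib1 (adjusted p = 0.0603). Markers of NK cells (12 of 15 higher, adjusted p = 0.766), dendritic cells (6 of 8 higher, adjusted p = 0.792), stroma and endothelium (8 of 17 higher, adjusted p = 0.693) and progenitors and pre-B cells (4 of 5 higher, adjusted p = 0.538) were not called. For NK markers the direction depended on the library left out. Without r_IbBM they were called as higher (adjusted p = 3.48e-07) and without r_IbSP as lower (adjusted p = 4.03e-07).

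Across the lists, 18 of 36 were called by camera with the preset correlation, 14 higher and 4 lower. With an estimated correlation 0 were called. Fry, which asks whether a list's genes move one way on balance, called 0 with a smallest adjusted p of 0.135. Fry's mixed test asks whether genes of a list change in either direction, again without comparing them with other genes. It passed for some lists that camera did not call. Adjusted p-values were 0.000432 for alternative NF-kB signalling, 0.000327 for the plasma cell programme and 0.000994 for B cell receptor signalling. It did not pass for heat shock (0.414) or G2/M (0.371), which camera called. Camera with an estimated correlation rests on the 2 residual degrees of freedom, so a lost call need not reflect correlation. FOXO and p53 targets lost theirs although their estimated correlations, -0.0189 and -0.00902, were below the preset 0.01. All other called lists had estimated correlations above the preset, from 0.0214 for G1/S and DNA replication to 0.997 for heat shock. Among them were the G2/M list at 0.940, ribosomal proteins at 0.734 and T cell markers at 0.664. For such lists the preset understates how far members vary together. Median, mean and test did not share a sign in 7 lists, none of them called. The median and mean log2 fold changes were 0.28 and -0.15 for alternative NF-kB signalling, -0.12 and 0.02 for PI3K signalling, -0.13 and 0.06 for G1 cyclins, 0.16 and 0.16 for the plasma cell programme, -0.05 and 0.18 for class II antigen presentation and 1.05 and 1.18 for NK markers, all with a test directed down. For stroma and endothelium they were -0.07 and 0.29, with a test directed up. Adjusted over the list alone, further members were higher in the lists for neutrophil precursors (3), class II antigen presentation (2), and NF-kB targets, p53 targets, glycolysis, megakaryocytes, dendritic cells, stroma and the plasma cell programme (1 each). Lower were 2 members of the plasma cell programme and 1 each of the lists for lymphoma identity, alternative NF-kB signalling and memory B cells, and 0 in the lists without a value here. Over all genes tested 0 members of any list passed.

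**Figure D2:**
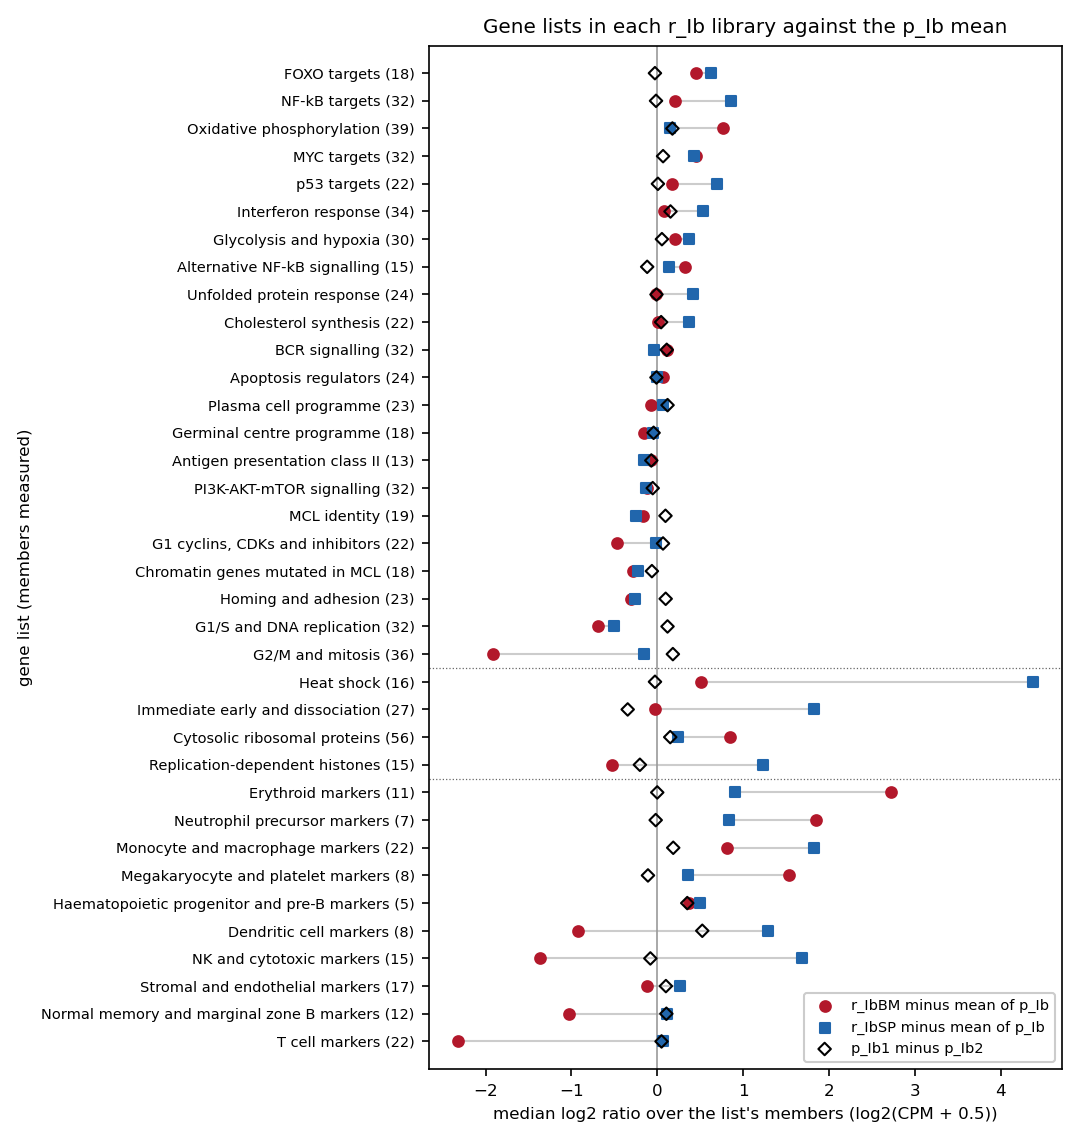
Median log2 ratio of each gene list in r_IbBM (red circles) and r_IbSP (blue squares) against the mean of the p_Ib libraries, with the ratio of p_Ib1 to p_Ib2 (open diamonds), on log2(CPM + 0.5). Dotted lines separate lists of lymphoma biology, of sample quality and of other cell types, with the number of measured members in brackets. G1/S and DNA replication lay at -0.69 and -0.51 in the r_Ib libraries, while heat shock lay at 0.51 in r_IbBM and 4.38 in r_IbSP.

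The r_Ib libraries were compared with each other to see how far samples of different source differed within the group, with 1 library on each side and hence no test or replicate check. In r_IbSP the heat shock genes stood far above their level in the other 3 libraries. HSPA1A, the inducible HSP70, stood at 13.3 CPM in r_IbBM and 19458 CPM in r_IbSP, and its near-identical neighbour HSPA1B, whose reads are hard to separate from it, at 25.1 and 20250 CPM. Together this pair took 3.84% of the counts in r_IbSP (95% exact binomial interval 3.83 to 3.84%), against 0.00370% in r_IbBM (0.00351 to 0.00391%), an interval that covers counting error alone. HSPA6, BAG3 and DNAJB1, further heat shock effectors, stood at 22.8, 2.73 and 51.0 CPM in r_IbBM and at 9326, 937 and 11319 CPM in r_IbSP. The other 3 of the 8 genes furthest above bone marrow were RASD1 (0.416 and 89.2 CPM), the interleukin receptor chain IL2RB (0.297 and 65.8 CPM) and the immediate early gene IER5 (67.0 and 5262 CPM). Genes furthest above spleen in r_IbBM were ERMN (74.3 and 3.62 CPM), LOC100131754 (80.2 and 9.08 CPM), HBB (301 and 35.8 CPM), SNX9 (230 and 30.4 CPM), TMEM88 (30.9 and 4.50 CPM), PAPD7 (265 and 42.3 CPM), MTSS1L (46.2 and 7.30 CPM) and the alpha-globin gene HBA1 (66.0 and 10.8 CPM). In all, 1507 of 9849 genes with a mean of at least 10 CPM differed by at least 2-fold, 685 higher in bone marrow and 822 higher in spleen.

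By gene list, all 16 heat shock members were higher in spleen, with a median log2 ratio of 4.04, and all 36 members of the G2/M list were higher there, with a median of 1.81. All 15 NK and cytotoxic markers were higher in spleen (median 3.35), as were 20 of 22 T cell markers (median 2.71) and 8 of 8 dendritic cell markers (median 2.07). Each of these medians lay at the 100th percentile of 10000 random lists matched on mean expression. Random lists lack the joint variation of a list's genes, so such a percentile does not measure how samples vary. Between p_Ib1 and p_Ib2 the dendritic cell list also lay at the 100th percentile (median 0.52) and G2/M at percentile 99.98 (median 0.18). Heat shock, NK and T cell lists lay there at percentiles 15.6, 36.5 and 87.9. Erythroid markers were higher in bone marrow at 10 of 11 members, with a median of 2.07 at the 100th percentile, and ribosomal protein genes at 53 of 56 members, with a median of 0.55 at the 100th percentile. The mantle cell lymphoma identity list had a median of 0.12 at the 29.6th percentile, and PI3K, AKT and mTOR signalling a median of 0.09 at the 38.8th percentile.

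The p_Ib libraries gave the difference between samples of 1 group and tissue, again without a test. Only 19 of 9710 genes with a mean of at least 10 CPM differed by at least 2-fold, 6 higher in p_Ib1 and 13 in p_Ib2, against 869 to 1463 in the 4 comparisons of a p_Ib with an r_Ib library. Higher in p_Ib1 were the zinc transporter SLC30A1 (39.3 and 11.0 CPM), the metallothionein MT2A (24.3 and 6.95 CPM), APOE (14.6 and 5.50 CPM) and the lysozyme gene LYZ (29.4 and 13.2 CPM). Higher in p_Ib2 were MAP1A (11.5 and 56.1 CPM), RBKS (12.7 and 36.9 CPM), MIAT (15.7 and 38.6 CPM), HSPA1A (6.66 and 16.5 CPM) and ZNF331 (151 and 346 CPM). RBKS and LYZ each overlap other listed loci. Immediate early and dissociation genes were lower in p_Ib1 at 22 of 27 members (median -0.34, at percentile 0 of the random lists). Ribosomal protein genes were higher in p_Ib1 at 53 of 56 members and oxidative phosphorylation genes at 37 of 39, with medians of 0.15 and 0.18 at the 100th percentile. Pearson's r across genes was 0.987 for the p_Ib pair, 0.936 to 0.941 between groups and 0.926 for the r_Ib pair, and genes are not independent replicates. The chi-square between the p_Ib libraries was 21.4 per degree of freedom over 15544 genes, so the files were not copies of each other. Separate preparations of 1 sample would also exceed counting noise, and only the labels set these libraries as 2 samples.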

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

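Alternatives chosen after seeing the data were leaving out the heat shock list before scaling, limma trend and the robust quasi-likelihood test, and each called 0 genes. Between r_Ib and p_Ib, 0 genes were also called under the stricter filter, DESeq2 size factors, upper quartile scaling, limma-voom, and without immunoglobulin and T cell receptor genes. With no filter 16 genes passed, among them the 10 named by the rule on p-values. At a threshold of 0.10 there were 12, with the DESeq2 Wald test 797 and with edgeR's exact test 509. The DESeq2 and exact tests shared 464 calls. Fits that left out a library gave 0 to 7589 calls, 0 without either p_Ib library, 6044 without r_IbBM and 7589 without r_IbSP. In those 2 fits the lone r_Ib library is assumed to vary like the p_Ib pair. Between 13 and 16 lists were called when a library was left out, and 16 to 19 under other filters and scalings, against 18. Camera with an estimated correlation called 0, as did fry's test for movement one way. Of the 18 lists called, 6 were called in the same direction whichever library was left out, namely G1/S and DNA replication, MYC targets, ribosomal proteins, erythroid, monocyte and neutrophil precursor markers. The direction turned without a call in any fit for class II antigen presentation, cholesterol synthesis, dendritic cell markers and the plasma cell programme. Adjusted p-values of the 3 other lists whose direction turned ran from 1.55e-10 to 0.789 for T cell markers, 3.48e-07 to 0.724 for NK markers and 7.08e-05 to 0.922 for replication-dependent histones. The histones were called as higher without r_IbBM and as lower without r_IbSP (adjusted p = 0.00770).

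Among the named genes, the log2 fold change took both signs when libraries were left out for CCND2 (-1.44 to 1.15), CDK6 (-1.12 to 0.62), SOX11 (-0.73 to 0.53), CXCR4 (-1.01 to 0.52), PLCG2 (-0.27 to 0.0785), CARD11 (-0.33 to 0.0522), CD5 (-0.20 to 0.46), PIK3CD (-0.0371 to 0.42) and TRAF3 (-0.40 to 0.73). With limma-voom the sign turned for CDK6 (-0.0494) and SOX11 (-0.10), and with limma trend for CCND2 (-0.13), CDK6 (-0.23) and SOX11 (-0.0839), and the cause was not tested. The other results for named genes under settings that kept every library kept their direction, 869 on the same side of the threshold and 113 newly past it. Genes at least 2-fold apart numbered 2784 between bone marrow and spleen and 78 between p_Ib1 and p_Ib2 with a minimum mean of 1 CPM, since more low genes enter, and stayed within 1462 to 1560 and at 19 under the other settings. A pseudocount does not enter the count tests, so its alternatives were not run for them. No paired analysis was possible because the labels give no donor and number only the p_Ib libraries. With 2 libraries per group at this spread, the simulated test missed most 2-fold changes, so a gene that did not pass is not shown to be equal between groups.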

Other observations

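The tests in this part were chosen after the results they concern were seen, except the match of ribosomal and respiratory chain genes on transcript length. Dendritic cell markers were not called between the groups, yet LILRA4, a receptor of plasmacytoid dendritic cells, stood at 3.54 and 1.92 CPM in p_Ib, 79.8 CPM in r_IbBM and 137 CPM in r_IbSP. CD1C, another member of that list that some B cells also express, stood at 95.8, 55.8, 10.3 and 29.4 CPM in the same order.

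Heat shock genes were higher in the spleen library than in the other 3, and took 8.66% of its counts against 0.344 to 0.432% elsewhere. Reads shared between near-identical copies do not account for this, since the median log2 ratio of spleen over bone marrow was still 3.05 over the 13 members without HSPA1A, HSPA1B and HSPA6. The median log2 ratio to p_Ib was 4.38 in the spleen library and 0.51 in the bone marrow library, the latter at the 99.2nd percentile of random lists. Stress of the cells during handling of this library is a candidate explanation, as the immediate early and dissociation list had a median log2 ratio of 1.85 over bone marrow, at the 100th percentile. That list also lay at percentile 0 for p_Ib1 over p_Ib2 (median -0.34), so the percentile alone cannot decide on this. A difference of the spleen tissue itself stays open, untested.

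Ribosomal protein and respiratory chain genes, both short (median transcript lengths of 754 and 824 bases against 2684 over all genes), were higher in r_Ib. Across 15898 genes, fold change had a Spearman's rho of -0.19 with transcript length, and genes are not independent replicates. For ribosomal proteins the median log2 fold change lay at percentile 99.0 of random lists matched on length and level. Random lists lack the joint variation of these genes, which reached the 100th percentile of level-matched lists even between p_Ib1 and p_Ib2 (median 0.15). The percentile thus cannot decide on a length bias. The r_IbSP library lay above the p_Ib mean at a median of 0.24. For the respiratory chain the median lay at percentile 80.4 of such lists, so a transcript length bias may account for it, and it also rested on the bone marrow library, since the median in r_IbSP was 0.15, at the 93.2nd percentile. A length bias and a difference of group or tissue stay open for ribosomal proteins, the latter untested.

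DNA replication genes were lower in r_Ib. Counts taken up by heat shock genes can lower other genes in the spleen library by at most -0.13 on the log2 scale, while the list's median there was -0.51 and its upper quartile -0.26. A lower share of B cells would raise markers of every other cell type alike only if the mix of those types stayed the same. In r_IbBM the log2 ratios to p_Ib of T cell markers (upper quartile -1.62) and of monocyte markers (lower quartile 0.11) lay apart. Other cell types thus did not rise alike there. This cannot decide on a lower share of B cells, since the mix of other cells may differ between tissues. In r_IbSP these quartiles overlapped (0.98 and 0.55), while the lower quartile of the T cell markers was -0.44. A rise of both marker types was thus not shown there either, and a lower share stays open in both libraries. Over both r_Ib libraries together, 11 B lineage genes had a median log2 fold change of -0.14 with a range of -1.16 to 0.37. Whether the tissue of the sample accounts for the difference cannot be told apart from the group, as the number of lymph node libraries in r_Ib was 0, and a lower replication programme in r_Ib remains a hypothesis.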
